A study of Gallus gallus with 2 samples.

How the data were processed

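Small RNAs of DF-1 chicken fibroblasts were sequenced in 2 libraries titled ARV_24 and NC_24, whose titles and infection labels contradict each other. Per the labels' protocols, total RNA was made into TruSeq Small RNA libraries, sequenced on an Illumina instrument, and the reads were passed through ACGT101-miR, which removed adapter dimers, low-complexity reads, repeats and common RNA families such as rRNA, tRNA, snRNA and snoRNA. The protocol speaks of more libraries than the 2 used here. The aligner, the genome build, the miRBase release and the way targets were predicted are not given in the sources used here.

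The deposited table lists 704 sequences with a name, the raw reads and the normalised reads of each library. Of these rows, 329 carry chicken names, 277 names of other species and 98 were predicted by the authors, and they hold 674 distinct sequences. 1 further line of the table was not used here. The raw values deposited by the authors are expected counts, since of the values above 0 exactly 107 of 655 in NC_24 (16.3%) and 78 of 310 in ARV_24 (25.2%) are not whole numbers, as when reads are shared between rows. Rows of near-identical family members can therefore exchange reads. No whole value of 1 or 2 occurs in either library (the smallest whole value above 0 is 3), so a listed 0 can stand for a few reads. The normalised values, a read signal per the file headers, are the raw values times 1 factor per library, 12.7 for ARV_24 and 0.557 for NC_24, and how the authors found the factor is not given. The fold deposited by the authors is the ratio of the normalised values, and the log2 column is its log2 per the file headers. The 2 p-value columns are, per the file headers, from a chi-square and a Fisher test. The pathway table of the authors gives numbers of genes and an enrichment p-value, neither adjusted for the number of pathways.

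The miRNA level was compared as the log2 ratio of the authors' normalised values, ARV_24 over NC_24. Its 95% interval is an exact Clopper-Pearson interval of the share of the pooled raw reads, rounded to whole reads. PCR copies are not independent molecules, so intervals and floors cover counting error only. A row at 0 in 1 library was given a bound with 3 raw reads in place of the 0 (38.0 normalised reads in ARV_24 and 1.67 in NC_24), and had no ratio where that bound lay on the other side of no change. A difference given as at least some fold rests on this bound, and the 95% limit of such a row lies nearer to no change. Counts of differing rows took rows with a pooled raw count of at least 20 and a difference of at least 2-fold. The table holds 1 library per title, so no p-value between conditions was computed, and Fisher's test on the reads of the 2 libraries was run only to set beside the deposited p-values. Families and lists were fixed before the data were examined, matched on the name without species and arm, and set against 10000 random lists matched in 10 classes of mean level (seed 1). Where a list was restricted to chicken-named rows the classes were fewer.

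The miRNAs named were chosen by a rule set before the data were examined: the 12 with the highest and the 12 with the lowest interval bound nearest to no change, the 5 most abundant in each library, and up to 4 of the highest mean level per list, each sequence or name once. For pathways they were the 10 of smallest p and those of virus sensing, infection, apoptosis, autophagy, MAPK, p53 and Jak-STAT signalling.

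Other scalings were CPM over all rows, edgeR TMM, size factors by the median of ratios, CPM without the 5 most abundant rows of either library and, added after the data were seen, reads scaled to the total of chicken-named rows. They move every log2 ratio by -0.38, -0.04, -1.12, 0.46 and 1.78 from the authors' scaling. A pseudocount of 1 added to the normalised values, limits of 1.5-fold and 4-fold, no count minimum, a minimum of 100, chicken-named rows alone and each sequence once were also tried, as were the mean of a list and its dominant arms. Fisher's test on raw reads and lists of chicken-named rows were added after the data were seen. Gene names and neighbours came from the RefSeq annotation of GRCg7b, and no coordinates are given because the build of the study is not known. Of 161 chicken names with a pooled count of at least 20, 156 had a gene in it.

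The interval and the counting rule were tested on simulated data before use. Each of 704 rows was drawn for NC_24 at the larger of its 2 raw read counts, and for ARV_24 at that level lowered by the authors' factors. The draws were whole Poisson counts in which 1 and 2 can occur, so the fractions and the missing low values of the deposited counts were not covered. Of the 704 rows 200 differed 4-fold, and 115 of the 200 had a ratio. The interval held the true ratio in 97.5% of rows read in both, 87.8% of the 115 were called at 2-fold or more with 0 in the wrong direction, and 11.9% of unchanged rows with a ratio were called, 2 of them with an interval that excluded no change. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.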

Results

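Small RNA sequencing was used to ask how the miRNA profile of DF-1 cells, a continuous line of chicken embryo fibroblasts, differs before and after infection with avian reovirus, a double-stranded RNA virus of poultry. The table held 2 libraries, 1 titled ARV_24 and 1 titled NC_24, and the sources used here do not say what the number in the titles stands for. The sample labels contradict the titles: the library titled ARV_24 carries the infection label untreated, and the library titled NC_24 carries the label avian reovirus. Libraries are therefore named by their titles, and every direction is between the titles, not between infected and uninfected cells. With n = 1 library per title there was no replicate check and no test between conditions, and the 95% intervals cover counting error only.

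The library titled NC_24 held 2853838 reads over the 704 miRNA rows of the table and the library titled ARV_24 held 163630, a 17.4-fold difference in depth. Reads were listed for 655 rows in NC_24 and for 310 rows in ARV_24, with 261 rows above 0 in both. Rows named for chicken miRNAs took 88.2% of the NC_24 reads (95% Clopper-Pearson interval 88.2 to 88.2) and 19.7% of the ARV_24 reads (19.5 to 19.9). Rows named for miRNAs of other species took 11.4% (11.4 to 11.5) and 67.5% (67.3 to 67.7), and rows predicted by the authors took 0.365% (0.358 to 0.372) and 12.8% (12.6 to 13.0). The most abundant row took 19.5% of the reads in NC_24 (19.4 to 19.5) and 27.7% in ARV_24 (27.4 to 27.9). The 5 most abundant rows took 42.5% (42.4 to 42.5) and 59.7% (59.5 to 59.9), and the 10 most abundant took 58.2% (58.2 to 58.3) and 72.7% (72.4 to 72.9). The identity of these leading rows differed. In NC_24 they were miR-100-5p, miR-125b-5p, miR-222a, miR-221-3p and miR-21-5p, all named for chicken. In ARV_24 they were 2 arms of mouse mir-6240, bovine miR-11980, mouse mir-6236-p5 and the predicted sequence PC-5p-154_22327. The 23 rows named for mir-6240 or mir-6236 together took 53.5% of the ARV_24 reads (53.2 to 53.7) and 0.515% of the NC_24 reads (0.507 to 0.523).

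**Figure D1:**
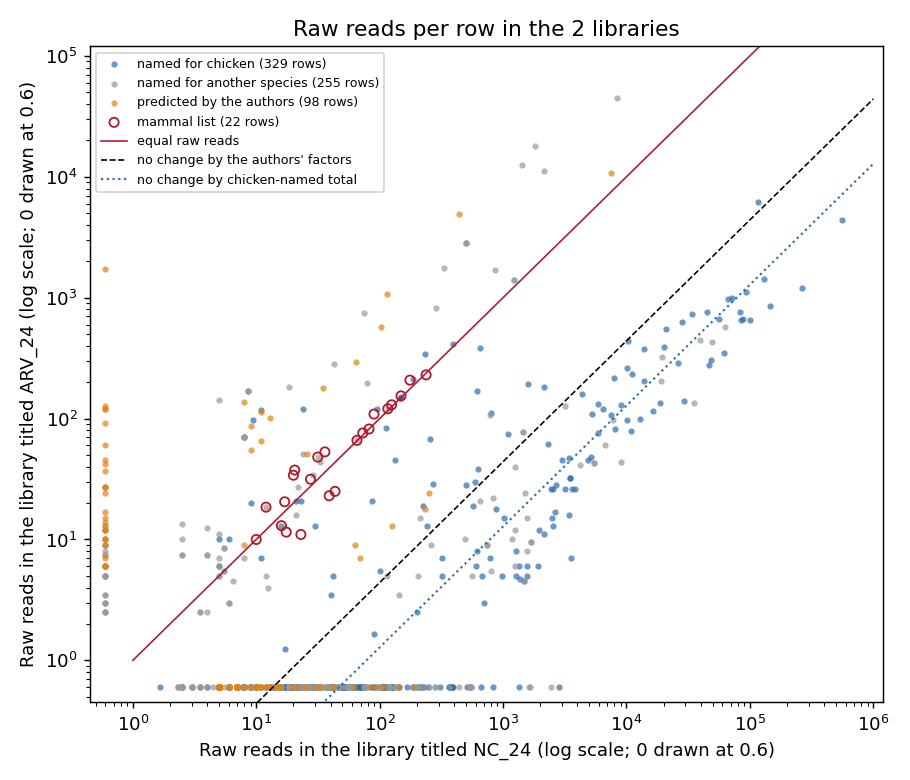
Raw reads per row in the library titled NC_24 (horizontal, log scale) against the library titled ARV_24 (vertical, log scale), 1 point per row, coloured by the kind of name, with a 0 drawn at 0.6 and the 22 sequences of a mammal list circled. The lines mark equal raw reads and no change under 2 scalings; most chicken-named rows with 1000 reads or more in NC_24 lie under the dashed line of the authors' factors and around the dotted line of the chicken-named total.

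The first comparison was of miRNA levels in the library titled ARV_24, labelled untreated, against that titled NC_24, labelled avian reovirus. By the authors' normalised read counts, 22 of 32 rows of fibroblast-associated miRNAs were at least 2-fold lower in ARV_24. The normalised read count of miR-125b-5p was 145929 in NC_24 and 15208 in ARV_24, which is 9.60-fold lower (9.07 to 10.2). miR-222a, which with miR-221 restrains the cell cycle inhibitor p27, was 7.56-fold lower (7.07 to 8.09), and miR-100-5p was 5.56-fold lower (5.40 to 5.73). miR-21-5p, a growth-linked miRNA, stood apart with 65321 normalised reads in NC_24 and 78330 in ARV_24, a log2 ratio of 0.26 (0.22 to 0.30) that turned to -0.12 with CPM and to -0.86 with the median of ratios. The median log2 ratio was -0.70 over all rows and -1.36 over chicken-named rows.

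Of the 432 rows with a pooled raw count of at least 20, 330 had a ratio that the depth allowed to be given. At least a 2-fold difference was seen in 254 rows, with 113 higher and 141 lower in ARV_24, and 76 rows lay within 2-fold. For 111 of the higher and 139 of the lower rows the counting interval excluded no change, and 43 of the lower rows were listed at 0 in ARV_24. The split followed the kind of name. Among chicken-named rows 24 were higher and 96 lower, among rows of other species 60 were higher and 43 lower, and among predicted rows 29 were higher and 2 lower. The scaling set much of this split. Size factors by the median of ratios gave 104 higher and 208 lower rows, and for chicken-named rows 20 higher and 140 lower. Scaling to the chicken-named total, chosen after the data were seen, gave 141 higher and 42 lower rows, and for chicken-named rows 42 higher and 28 lower around a median of -0.06.

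The chicken miRNAs with the largest deficits in ARV_24 came from several families. miR-10c-5p, encoded among the Hox genes, had 2850 raw reads in NC_24 and was listed at 0 in ARV_24, at least 41.8-fold lower after scaling. miR-454-3p, of sequence TAGTGCAATATTGCTTATAGGGTCT in the table, had 3541 and 7 raw reads, a log2 ratio of -4.47 (-5.79 to -3.43). miR-27b-5p was at least 19.7-fold lower, miR-2131-5p at least 12.1-fold and miR-146c-3p at least 9.71-fold. Rows carrying names of other species were also among the lowest: miR-2954-5p was at least 36.1-fold lower, let-7f-3p at least 24.1-fold and miR-222a-5p at least 23.6-fold, each listed at 0 in ARV_24. miR-23a-3p, under its anole name, had a log2 ratio of -3.52 (-3.78 to -3.27), and under its human name, with more reads, one of -2.32 (-2.46 to -2.19). That of miR-146c-5p was -3.19 (-3.44 to -2.96). These directions also held under each of the 5 other scalings for the rows with reads in both libraries, and relative to the chicken-named total miR-454-3p stood at -2.69, miR-125b-5p at -1.48 and miR-146c-5p at -1.41.

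The rows highest in ARV_24 relative to NC_24 were 10 predicted sequences and 2 rows named for mouse miRNAs. PC-5p-3170_1297 had 1720 raw reads in ARV_24 and was listed at 0 in NC_24, at least 13045-fold higher after scaling. PC-5p-24801_106, PC-5p-25320_103 and PC-5p-43168_46 had 126, 120 and 119 raw reads in ARV_24 and were listed at 0 in NC_24. The same held for PC-5p-41224_50 with 92 reads, PC-3p-40451_51 with 60, PC-5p-43908_45 with 45, PC-5p-88398_12 with 42 and PC-3p-88784_12 with 37. PC-5p-627_6301 was read in both libraries, with a log2 ratio of 7.97 (7.83 to 8.12). miR-2137 had 5 raw reads in NC_24 and 142 in ARV_24 (log2 ratio 9.34, 8.08 to 10.98). The leading mir-6240-p5 row reached 7.81 (7.74 to 7.88), mir-6240-p3 6.93 (6.90 to 6.97), miR-11980 7.66 (7.58 to 7.74), mir-6236-p5 6.87 (6.81 to 6.94) and PC-5p-154_22327 5.01 (4.96 to 5.05).

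The second comparison was of miRNA families and of lists for cell types and pathways, again between the libraries titled ARV_24 and NC_24, whose infection labels contradict these titles. By the authors' scaling, under which 96 of 169 chicken-named rows were at least 2-fold lower in ARV_24, no row was at least 2-fold higher in 6 families as listed, of which the let-7 list leaves out let-7e (3.71 under its human name, from 43.5 and 25 raw reads). The miR-17-92 list leaves out miR-25 (4.56, from 149 and 154 raw reads) and miR-93 (4.51, from 82 and 82), both under mammal names. Relative to the chicken-named total the medians of the 6 families were 0.20 for let-7, -0.10 for miR-17-92, -0.21 for miR-23/24/27, -0.49 for miR-30, -1.02 for miR-181 and -1.07 for the family of miR-130, miR-301 and miR-454. These last 2 medians rest on 4 rows each, against 5 and 9 by the authors' scaling, because rows listed at 0 in ARV_24 lost their bound. For the same reason let-7 went from 16 to 13 rows, miR-17-92 from 18 to 13 and miR-23/24/27 from 12 to 10. Over chicken-named rows alone the medians relative to that total were 0.46 for let-7, 0.21 for miR-17-92 (10 rows) and 0.01 for miR-181 (3 rows). They were -0.37 for miR-23/24/27 (4 rows), -0.49 for miR-30 and -1.07 for the miR-130 family. In contrast, 7 of 8 rows of blood-cell miRNAs were at least 2-fold higher, with a median log2 ratio of 4.44. Each list is described by its median log2 ratio and, where it has at least 3 rows, by the percentile of that median among 10000 random lists of the same size and level. Rows listed at 0 in ARV_24 enter these medians at the 3-read floor. They were 6 of 16 rows for let-7, 8 of 18 for miR-17-92, 4 of 12 for miR-23/24/27 and 4 of 8 for miR-15/16. Such rows were also 6 of 9 for the miR-130 family, 8 of 32 for fibroblast-associated and 4 of 17 for immune-response miRNAs. For neural and liver miRNAs they were 3 of 6, and any other list had at most 1. The percentile describes these libraries only, and it is also given with the list and its background restricted to chicken-named rows, chosen after the data were seen. Against that background 1 list of a family or pathway, immune-response miRNAs, lay under percentile 10.

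Of 32 fibroblast-associated rows, 22 were at least 2-fold lower, 2 higher and 8 between, with a median of -1.81 at percentile 1.58. Among chicken-named rows the list's median was also -1.81 and its percentile 30.9, and relative to the chicken-named total the median of the list was -0.27. miR-221-3p was among the lower ones, at -2.01 (-2.08 to -1.93). The group of miR-10, miR-99, miR-100 and miR-125, of which 8 rows are also fibroblast-associated, had 9 of 11 rows lower, 2 higher and a median of -2.19 (percentile 10.1), and -1.95 (percentile 44.7) among chicken-named rows, or -0.41 relative to the chicken-named total. miR-99a-5p stood at -2.52 (-2.63 to -2.41). All 8 rows of the miR-30 family outside 2-fold were lower, among 10 rows with a median of -2.27 (percentile 2.98), and the same median was at percentile 20.9 among chicken-named rows. Over the dominant arm of each member, 5 rows, the median was -1.59. miR-30c-5p at -2.79 (-2.96 to -2.63) and miR-30d at -2.77 (-2.88 to -2.66) were further from 0 than miR-30a-5p at -1.59 (-1.68 to -1.50) and miR-30e-5p at -1.17 (-1.32 to -1.02), and these last 2 were above 0 relative to the chicken-named total. The family of miR-130, miR-301 and miR-454, counted over both arms, had 7 of 9 rows lower, and 6 of the 9 stand at the 3-read floor. Its median was -1.75, at percentile 0.760, against -1.80 at percentile 33.0 among chicken-named rows. In this family miR-130b-3p stood at -2.59 (-2.93 to -2.27).

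The let-7 family, regulators of differentiation timing, had 10 of 16 rows lower and a median of -1.32 (percentile 12.5), which turned to 0.20 under the chicken-named total. Among chicken-named rows its median was -1.05, on the high side at percentile 79.8. Its rows read in both libraries spread from let-7k-5p at -3.24 (-4.05 to -2.54) over let-7b at -1.58 (-1.78 to -1.38), let-7g-5p at -1.03 (-1.14 to -0.93) and let-7f-5p at -0.04 (-0.18 to 0.10) to let-7d-3p, under its pigeon name, at 0.69 (-0.18 to 1.44). Relative to the chicken-named total let-7k-5p, let-7l-5p and let-7c-5p stayed under 0 (-1.46, -0.64 and -0.32) and the other 7 were above 0. The proliferation-linked miR-17-92 cluster and its paralogues as listed, without the higher miR-25 and miR-93, had 10 of 18 rows lower and a median of -1.17 (percentile 6.64, but 68.0 among chicken-named rows). In it miR-92-3p stood at -1.88 (-1.96 to -1.79) and miR-20b-5p at -1.26 from 6490 and 119 raw reads, the latter above 0 relative to the chicken-named total. The miR-23/24/27 clusters had 9 of 12 rows lower (median -1.65 at percentile 12.1, but -1.66 at percentile 63.6 among chicken-named rows). Its rows read in both libraries spread from the anole-named miR-23a-3p given above to miR-27a-3p at 0.28 (-0.07 to 0.62), with miR-23b-3p at -2.64 (-2.91 to -2.37), miR-27b-3p at -1.66 (-1.75 to -1.57) and miR-24-3p at -0.68 (-0.83 to -0.53). Relative to the chicken-named total the rows of miR-23a-3p and miR-23b-3p stayed under 0. Those of miR-24, miR-27a and miR-27b read in both libraries were above 0. miR-27b-5p, listed at 0 in ARV_24, stayed at or under -2.52. The miR-181 family had 3 of 5 rows lower (median -1.77, percentile 14.3, and 52.0 among chicken-named rows). In it miR-181a-2-3p, under its pigeon name at -3.84 from 1467 and 4.5 raw reads, has the same reads as a chicken-named row that is also counted. The miR-15/16 family split, with 4 of 8 rows lower, 1 higher and a median of -1.54 (percentile 7.60), -2.43 (percentile 11.6) among chicken-named rows and -0.68 relative to the chicken-named total. miR-16c-5p stood at -2.50 (-2.80 to -2.22) and miR-16-5p at 1.47 (1.25 to 1.69). The group of miR-26, miR-101 and miR-148 as listed had 5 of 9 rows lower and 2 higher, with a median of -1.07 (percentile 45.3, and 70.2 among chicken-named rows). It leaves out miR-26b (4.46, from 238 and 230 raw reads), under a mammal name. Under the chicken-named total the median turned to 0.30 over the group but was -0.20 over its 6 chicken-named rows. In it, miR-148a-3p stood at -2.97 (-3.13 to -2.82) and miR-26a-2-5p at -0.99 (-1.11 to -0.88), which was 0.79 relative to the chicken-named total. The 2 rows of the collagen-repressing miR-29 family went apart, with miR-29a-3p at 3.72 (3.53 to 3.90) and miR-29b-1-5p listed at 0 in ARV_24 against 167 raw reads, at or under -1.29.

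Immune-response miRNAs had 9 of 17 rows lower, 2 higher and 6 between, with a median of -2.06 at percentile 3.36, and 8 of the list's rows are also fibroblast-associated. Among chicken-named rows the median was -2.28 at percentile 9.36, and relative to the chicken-named total the median of the list was -0.49. miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, was 4.84-fold lower in ARV_24 (4.51 to 5.20), a log2 ratio that was also -0.49 relative to that total. miR-155, an immune activation miRNA chosen after its value was seen, had 503 and 28 raw reads, a log2 ratio of 0.34 whose interval (-0.26 to 0.89) holds no change. Of the p53-associated list, rows of miR-192 and miR-194 alone had a ratio, with 2 of 3 higher, a median of 4.21 (percentile 82.1) and 59 ARV_24 reads in all. The 2 higher rows carry mammal names, miR-192 with 22 and 27 raw reads and miR-194-5p with 16 and 13, while the only chicken-named row, miR-194, stood at 0.95 (0.20 to 1.63). The median was 1.46 with the median of ratios, where 4 rows had a ratio.

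Among lists of other cell types, blood-cell miRNAs stood at percentile 90.1, and at percentile 99.2 among chicken-named rows (5 rows, median 4.51). Several of these miRNAs had nearly equal raw reads in both libraries despite the difference in depth. miR-451, an erythroid miRNA, had 395 raw reads in NC_24 and 416 in ARV_24 (log2 ratio 4.58, 4.38 to 4.79), miR-486, under its dog name, 176 and 208 (4.75, 4.45 to 5.05), and the endothelial miR-126-3p 150 and 150 (4.51, 4.17 to 4.84). The intervals of 9 of 226 chicken-named rows hold the pooled raw ratio of 1.06 of 22 mammal-named sequences on a list drawn up after the table was seen, of which miR-486 is 1, and 4 of the 9 are on the blood-cell list: miR-451, miR-126-3p, miR-126-5p and miR-142-5p. The myeloid miR-223 was higher by less, at 1.68 (1.38 to 1.96). The liver miRNA miR-122-5p had 145 and 149 raw reads (4.55, 4.21 to 4.89), within a neural and liver list of 6 rows that went both ways, 2 higher and 3 lower, with a median of -1.50 (percentile 30.1, and 44.8 among chicken-named rows), -0.34 relative to the chicken-named total, and a mean of 0.04. In that list the neural miR-128-3p stood at -2.12 (-2.46 to -1.81). Epithelial miRNAs had 3 of 6 rows higher and 2 lower, and their median of 1.33 (percentile 56.9, and 95.4 among chicken-named rows) turned to -0.10 with CPM and to -0.84 with the median of ratios, and was 3.11 relative to the chicken-named total. miR-200b-3p stood at 2.58 (2.18 to 2.97) and miR-429-3p at -1.58 (-2.42 to -0.85), the latter above 0 relative to the chicken-named total. The only muscle row, miR-133a-3p, had 40 and 3.5 raw reads (0.99, -0.76 to 2.65), and the cluster of miR-302 and miR-367 had no row in the table. miR-133a-3p lay near the 3-read floor in ARV_24, and a difference of its size was not detectable at this depth.

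**Figure D2:**
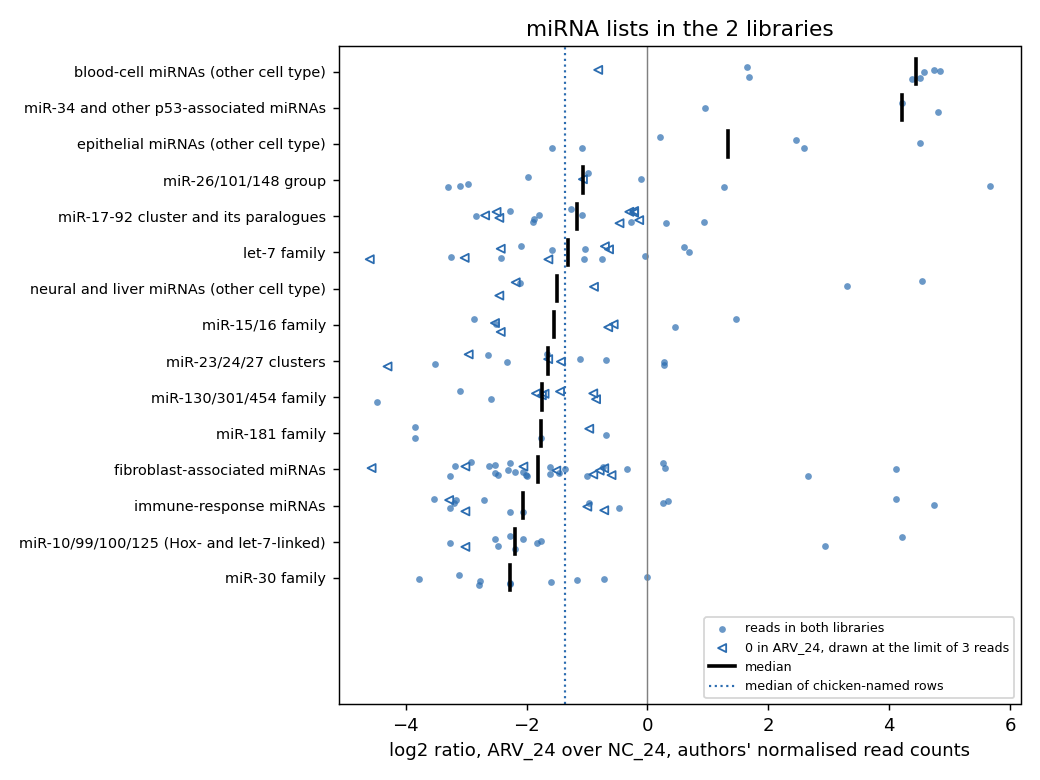
Log2 ratio of the authors' normalised read counts, the library titled ARV_24 over that titled NC_24, for the rows of each list with at least 3 ratios, with filled points for rows read in both libraries, open triangles for rows listed at 0 in ARV_24 drawn at the 3-read floor, and a black bar at the median. Blood-cell miRNAs lie around 4.44 and the miR-30 family around -2.27, and the medians of let-7 and of the miR-26, miR-101 and miR-148 group turn above 0 under the chicken-named total while that of epithelial miRNAs turns under 0 with CPM and the median of ratios.

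The authors' deposited table called 179 rows up in ARV_24, 492 down and 33 neither. These calls follow the fold alone, from 2.18-fold upwards and from 0.498-fold downwards: 394 rows called down were listed at 0 in ARV_24, 49 called up were listed at 0 in NC_24, and 89 called rows of the authors' deposited table have a Fisher p above 0.05, up to 0.434. The Fisher p-value of the authors' deposited table was at or under 0.05 in 604 rows and its chi-square p-value in 628. These p-values compare the 2 libraries and not the conditions. Fisher's exact test, two-sided, on the rounded normalised values gave the deposited p within 0.01 on the log10 scale in 528 of the 528 rows with p above 1e-100, and on the raw reads in 0 of 528. On the raw reads, 376 of 704 rows were at or under 0.05. Among the 394 rows listed at 0 in ARV_24 the number went from 305 with the deposited p to 86 with the raw reads. Normalisation multiplied each ARV_24 read by 12.7 and each NC_24 read by 0.557 before that test.

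The third comparison was of KEGG pathways among predicted target genes, as the authors' deposited table lists them; the sources used here do not say which miRNAs the targets are of. Protein processing in the endoplasmic reticulum led the list, with 69 of its 74 genes among the predicted targets (Fisher's exact test of the authors' deposited table, p = 0.00231), followed by tight junction with 53 of 57 (p = 0.00931), oocyte meiosis with 45 of 48 (p = 0.0112), Notch signalling with 21 of 21 (p = 0.0116) and glycolysis with 29 of 30 (p = 0.0138). DNA replication (18 of 18, p = 0.0220), NOD-like receptor signalling and SNARE interactions (16 of 16 each, p = 0.0337), the spliceosome (50 of 55, p = 0.0343) and arginine and proline metabolism (31 of 33, p = 0.0348) completed the first 10 by the same exact test of the authors' deposited table. Apoptosis had 37 of 40 genes among the targets (exact test of the authors' deposited table, p = 0.0378).

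Of the 160 pathways in the authors' deposited table, 14 had p under 0.05, where 8 would be expected by chance at most, and 0 had a Benjamini-Hochberg adjusted value under 0.05. The smallest adjusted value was 0.370, from a one-sided hypergeometric test that gave the deposited p-values again. The target set held 1681 of the 2076 background genes, 81.0%, so that no pathway could exceed the background share by more than 1.23-fold. Among pathways of virus sensing and infection, p of the authors' deposited exact test was 0.236 for cytosolic DNA sensing, 0.652 for influenza A, 0.511 for herpes simplex, 0.412 for Salmonella infection, 0.878 for Toll-like receptor and 0.960 for RIG-I-like receptor signalling. It was 0.328 for p53 signalling, 0.351 for autophagy, 0.551 for MAPK and 0.983 for Jak-STAT signalling.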

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

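The chicken-named total, the Fisher test on raw reads and the lists of chicken-named rows were chosen after the data were seen. The median log2 ratio over all rows, -0.70 by the authors' scaling, was -0.96 with CPM, -1.24 with the median of ratios, -0.33 with CPM without the 5 most abundant rows, -2.81 with a pseudocount of 1, and 1.21, reversed, under the chicken-named total. The median of chicken-named rows, -1.36, was -1.47, -2.01, -1.12, -3.60 and -0.0633 under these settings. Each scaling adds 1 constant to every ratio, and it also sets which rows listed at 0 in ARV_24 have a bound, so medians rest on different rows. The 141 lower rows became 42 under the chicken-named total, 92 at 4-fold and 286 with a pseudocount of 1. The pseudocount gives every row at 0 a ratio and brings the total of 254 to 399. It was added to the normalised values, so a row at 0 in ARV_24 stood at 1 normalised read. That is far under the 38.0 of the 3-read floor and makes such rows look lower. The 113 higher rows became 179 with no count minimum and 65 with a pooled count of at least 100, since more or fewer low rows are counted. Chicken-named rows alone gave 120 rows, 24 of them higher. The totals and splits under TMM, 1.5-fold and each sequence once stayed within 1.5 times.

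Among lists, the miR-29 family median of 1.21 over 2 rows turned to -0.36 with CPM, -0.0106 with TMM and -1.09 with the median of ratios. In each case 1 more row listed at 0 in ARV_24 entered, which makes 3. The median was -5.26 with a pseudocount of 1, where that row also entered and rows listed at 0 were no longer held at the 3-read floor. Epithelial miRNAs turned from 1.33 to -0.10 with CPM and -0.84 with the median of ratios, where 7 rows in place of 6 had a ratio. Under the chicken-named total, let-7 turned to 0.20 and the miR-26, miR-101 and miR-148 group to 0.30, where the 6 chicken-named rows of that group gave -0.20. Of 17 lists 1 turned sign with the mean in place of the median, neural and liver miRNAs at 0.0367, and 0 did with dominant arms. Sizes changed: immune-response miRNAs, at -2.06, had a mean of -1.19 and a median of -2.72 over dominant arms. The group of miR-10, miR-99, miR-100 and miR-125, at -2.19, had a mean of -1.30 and a median of -2.28 over dominant arms. Of the named miRNAs at least 2-fold apart, 9 turned sign, all under the chicken-named total: let-7b 0.20, let-7g-5p 0.75, miR-181b-5p 0.0140, miR-183 0.69, miR-20b-5p 0.52, miR-27b-3p 0.12, miR-30a-5p 0.19, miR-30e-5p 0.61 and miR-429-3p 0.20, by the constant of 1.78. None of those at least 2-fold apart turned under the other 4 scalings.

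Of the 14 pathways, 2 had p under 0.01 and 0 an adjusted value under 0.05. The 604 rows with a deposited Fisher p at or under 0.05 became 376 on raw reads. No paired analysis was possible because there is 1 library per title. Depth limits ARV_24 most: 102 rows with a pooled count of at least 20 had no ratio because 3 reads in ARV_24 are worth 38.0 normalised reads.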

Other observations

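The mammal list, the comparison of neighbouring and renamed genes, the resampling and the removal of rows with a snoRNA symbol, and the tests of a fixed number of foreign reads, of foreign RNA in proportion to depth, of overlapping rows and of unscaled shares were chosen after the result was seen. The tests of chicken genes for mammal names, of 1 common dilution and of miRNAs numbered 1300 and above were set before their results were seen.

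Among chicken-named rows, some not yet described stood far from the others. miR-1434 had 234 raw reads in NC_24 and 344 in ARV_24, miR-3538 had 113 and 83, and the mir-3535-p3 row had 24 and 120. 2 other rows of these genes were mir-1434-p3, with 65 and 0 raw reads and no ratio, and miR-3535, with 42 and 5 and a log2 ratio of 1.44. The GRCg7b annotation gives the genes of these 3 miRNAs the symbols of small nucleolar RNAs, SNORD37, SNORD83A and SNORD20. miR-1454 had 185 and 214 raw reads, and miR-142-5p, a blood-cell miRNA, 95 and 120. By contrast the smooth-muscle miRNA miR-143-3p had 612 and 170, a log2 ratio of 2.66 (2.41 to 2.91), while miR-145-5p, its usual partner, had 320 and 7, at -1.01 (-2.33 to 0.05). These miRNAs were chosen after their values were seen.

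Neighbouring miRNA genes, at most 10 kb apart in that annotation, did not stand out as moving together. Over 12 pairs among 18 abundant miRNAs the median absolute difference of log2 ratios was 0.89, against a median of 1.09 in 10000 shuffles, at percentile 25.9. miR-99a-5p and let-7c-5p were close (-2.52 and -2.10), as were miR-15c-5p and miR-16c-5p (-2.87 and -2.50), while miR-130b-3p and miR-454-3p (-2.59 and -4.47) and miR-30b-5p and miR-30d (-0.72 and -2.77) were apart.

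Some miRNAs carrying mammal names had nearly equal raw reads in both libraries: over 22 sequences of a list drawn up after the table was seen, among them miR-486, miR-26b, miR-25, miR-99b and miR-93 (82 and 82 reads), the pooled ratio was 1.06 (0.984 to 1.14), against 0.0128 for chicken-named rows. Of the 73 other mammal-named sequences the intervals of 5 hold that ratio, and many lay far from it, such as human-named miR-23a-3p with 49246 and 432 reads and miR-11980 with 1413 and 12556. For the 22 it is 18.5 times the ratio of the library totals, and 0 of their intervals hold the latter. As the list was drawn up after the table was seen, this repeats the observation and cannot decide on foreign RNA in proportion to depth. A fixed number of foreign reads per library is a candidate explanation that stays open: 81.8% of the intervals (18 of 22) hold the pooled ratio, but this repeats the observation on a chosen list, and the intervals of 9 of 226 chicken-named rows hold that ratio. Production by the chicken cells was set against the chicken annotation, where 9.52% of the mammal names (2 of 21, let-7e and miR-125a) have a gene, but it stays open because the bound set for excluding it was wrong: miR-23a has no gene there either and was read 84211 times in NC_24.

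Rows named for mir-6240 and mir-6236 and predicted sequences took most reads of ARV_24. All 121 rows with these names, whatever their values, held 66.3% of its raw reads and 0.880% of those of NC_24, a 75.3-fold difference in unscaled share (35.1-fold for the 98 predicted rows alone). The scaling, 1 factor per library, cannot change a share within a library, so this value restates the observation and could not have come out otherwise. Pieces of longer RNAs that passed the removal of common RNA families are a candidate source: 57.3% of their ARV_24 reads lie in rows whose sequence overlaps another with its start shifted by 3 bases or more, against 0.368% for chicken-named rows. Without mir-6240-p3, which alone holds 27.7% of the library, the value is 26.7%, so the test leaves this open. Whether infection or RNA quality differs with it was not tested, and the contradictory labels would leave the direction unknown.

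Chicken-named miRNAs were lower in ARV_24, and of the 76 such rows with 1000 reads or more in NC_24, 23.7% (18 rows) had an interval holding their pooled raw ratio of 0.0117, with 24 wholly above and 34 wholly below. The bound set for excluding 1 common dilution was wrong by the design: these intervals cover counting error only and 1 library per title gives no spread between libraries, so a dilution stays open. For foreign reads of conserved miRNAs counted as chicken ones, the read ratio of 146 rows numbered 1300 and above was 2.55 times that of the others (0.925 to 10.8 over resampled rows), and 1.43 times (0.536 to 5.58) without the 7 rows whose gene has a snoRNA symbol. The bound set for this one was wrong too, as it left out the spread between rows, and such reads would raise conserved rows rather than lower any, so they stay open as an addition to those rows. A difference between infected and uninfected cells stays open, untested with 1 library per title.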
